A study of Homo sapiens with 12 samples.

How the data were processed

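RNA from SZ95 sebocytes was sequenced in 12 libraries, 3 for each of LA, LA with RVT, PGN, and PGN with RVT, and groups and replicate numbers were taken from the sample titles. The authors deposited 2 tables of TPM, one per stimulus, with 1 column per library rounded to 2 decimals, as checked on the column names in the file headers. Per the submitters' processing notes, HISAT2 2.1.0, RSEM 1.3.1, DESeq2 1.24.0 and the build GRCh38.p13 were used, with no role or order given, and the annotation release is not given in the sources used here. The deposited TPM columns summed to between 994373 and 997060. TPM divides by transcript length and by the library's total, so it holds shares and no depth: a gene can lose TPM because others gained, and no interval from counts can be given. The table of LA libraries holds 60671 genes and that of PGN libraries 60666 genes, of which 60630 identifiers are in both, and 1432 of these carry different gene names, so the tables were made with different annotations. Symbols are those of the tables. Positions, gene types, GC content and length (of the longest transcript) came from GENCODE 29 on GRCh38, matched by identifier, and 99.2% of tested genes had a value.

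The tests had been planned before the data were examined, with a count model as the first choice and a second for normalized values. Since the tables hold TPM and no counts, the second was used. Values were transformed as log2(TPM + 1), genes with a mean of at least 1 TPM over the libraries of the fit were kept, and group differences were tested with limma 3.58.1 in R 4.3.3 (trended prior variance, no robust option), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each RVT comparison used its own 6 libraries. The difference of the RVT effects used 12 libraries with one mean per group, on genes in both tables. The plan made this conditional on a common scale; it was run because each TPM library is scaled by itself and the difference is formed from differences within a table. LA against PGN, also planned, was not tested, because a gene's TPM depends on the gene models and these differ between the tables, so levels in different arms are set side by side only. The replicates are described as biological, but nothing says whether they came from separate culture days, and p-values measure the spread between these libraries.

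The 27 gene lists were fixed before the data were examined, 5 of them for other cell types and 3 for RNA composition. Lipid and sebaceous lists were fatty acid and triglyceride synthesis, cholesterol synthesis and uptake, lipid droplet and lipolysis, fatty acid oxidation and PPAR targets, AMPK complex and regulators and sebocyte differentiation. Signalling and defence lists were inflammatory cytokines and NF-kB targets, pattern recognition receptors and adaptors, interferon response, NRF2 targets, aryl hydrocarbon receptor targets and p53 targets. Further lists were DNA replication and S phase, mitosis and G2/M, integrated stress response and unfolded protein response, hypoxia and glycolysis, autophagy and lysosome, estrogen receptor targets and immediate early genes. Those for other cell types were keratinocyte and squamous differentiation, fibroblast markers, melanocyte markers, immune cell markers and endothelial markers, and those for RNA composition mitochondrially encoded genes, cytosolic ribosomal proteins and replication-dependent histones. Of their 640 distinct symbols, 621 were found in each table. Lists with at least 5 tested members were tested with camera (preset correlation of 0.01) and with fry, adjusted over the lists of one comparison. Camera compares a list with the other genes, and fry asks whether a list's genes move on balance one way. Fry called 18 of 22 lists in the LA arm, 17 of 23 in the PGN arm and 18 of 23 in the difference, where camera called 11, 12 and 11. With an estimated correlation, camera kept the replication list in the LA arm, no list in the PGN arm, and 5 lists in the difference (inflammatory, cholesterol, interferon, hypoxia and immediate early). Some lists that lost their call had an estimate above the preset, such as ribosomal proteins in the LA arm (0.379). Others had one below it, such as immediate early genes in the LA arm (0.0048) and hypoxia genes in the PGN arm (-0.042). A call lost this way therefore does not by itself show correlation within the list. An arm was fitted on 6 libraries and the difference on 12, so the numbers of lists kept do not rank the comparisons. Named genes were chosen by a rule fixed before the data were examined. In each arm it takes the 8 largest rises and the 8 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 TPM in the higher group and no overlap between groups. For the difference it takes the 5 largest in each direction past the threshold with at least 5 TPM in the highest group. The rule also allows up to 4 members with the smallest p from any list described, and PRKAA1, PRKAA2 and SIRT1 are always given. After a first run the allowance was reduced, to shorten the text: 4 members from the called lists of lipid synthesis and inflammation, 2 from the other called lists, and none for the difference. Some genes that the rule selects are not reported here, and no others were taken in their place. CXCL8, IL6, CD74, CDH5 and the other cell type markers given by name were added after their values were seen.

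The fits were tested on simulated data built from each gene's real mean and spread, with 200 changed genes. A further 25 genes were shifted together as a set, and recovery is given for the 200. All changed genes had a mean log2(TPM + 1) above that of 5 TPM, so recovery of lower genes is not known. The noise was normal, as limma assumes, and independent between genes, so the share of false calls need not hold for the real libraries. In the simulated LA arm (15180 genes) limma recovered 67.2% of those changed by 0.5, 95.5% of those changed by 1, 100.0% of those changed by 2 on the log2 scale, and 5.31% of calls were false. In the simulated PGN arm (14430 genes) it recovered 70.1% of those changed by 0.5, 92.5% of those changed by 1, 100.0% of those changed by 2, with 3.98% false, and for the simulated difference (14921 genes) 44.8% of those changed by 0.5, 85.1% of those changed by 1, 98.5% of those changed by 2, with 3.03% false. Within the groups no replicate repeated another: at most 1.04% of tested genes had identical values in a pair. Pairs across groups were not compared. All genes called in an arm had non-overlapping groups. In the LA arm 36.2% and in the PGN arm 36.1% of tested genes had such groups, where chance gives 10%. Alternatives to each choice were a scaling that equalises the median log2 value of the libraries, no filter, a filter of at least 5 TPM, a pseudocount of 0.1, the replicate number as a block, one fit of all 12 libraries, and leaving out each library. Removal of mitochondrial genes and removal of GC and length trends were added after the data were seen. Splits of the libraries other than the labelled one were also fitted. Figures were drawn with matplotlib 3.10.9.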

Results

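Whole-transcriptome RNA sequencing was carried out on SZ95 sebocytes, an immortalised human cell line derived from the sebaceous gland. The 12 libraries fall into 4 groups of 3, which the design text describes as biological replicates. Cells were treated with LA, with LA and RVT, with PGN, or with PGN and RVT. The series title identifies RVT as resveratrol, a plant polyphenol, and names lipid accumulation, inflammation and AMPK signalling as the topics of the study. LA and PGN are not spelled out in the labels and are read here as linoleic acid, a fatty acid used to load sebocytes with lipid, and bacterial peptidoglycan, an inflammatory stimulus. No untreated group is among the labels, so the effect of either stimulus alone cannot be read from these libraries. Expression was deposited as TPM (expression scaled to transcript length and to the total of the library), in one table for the LA libraries and another for the PGN libraries. Between 14489 and 15452 genes reached 1 TPM in a library. TPM keeps no record of sequencing depth, so the depth of each library is unknown here and no counting interval is given. Values are mean TPM ± SD with n = 3 per group, and log2 fold changes are on the log2(TPM + 1) scale, which understates the change of low genes, with the standard error (SE) of the limma fit.

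The first comparison set LA with RVT against LA alone, and asked what resveratrol did to sebocytes under the lipid stimulus. As lists tested with camera, DNA replication and ribosomal protein genes were lower with RVT and immediate early and mitotic genes higher, with 18 of 40, 54 of 73, 12 of 18 and 15 of 40 members called. Only the replication list kept its call with an estimated correlation (adjusted p = 0.0283, against 0.119, 0.0648 and 0.119 for the others). PCNA, the DNA polymerase clamp, fell from 421 ± 8.38 to 309 ± 11.6 TPM (n = 3 per group), and EGR1, an immediate early transcription factor, rose from 23.0 ± 1.54 to 68.1 ± 1.22 TPM. CYP1B1, a cytochrome P450 induced through the aryl hydrocarbon receptor, fell from 14.2 ± 2.32 to 1.07 ± 0.320 TPM. Of 15409 genes tested with limma, 1645 were higher and 781 lower with RVT at an adjusted p under 0.05, and 80 of these changed at least 2-fold (32 higher and 48 lower). The excess of higher genes depended on the scaling: with the median log2 value of the libraries equalised, 1041 were higher and 1080 lower. The total of 2426 fell to 1610 without a filter, and to 1459, 1428, 1463 and 1546 without LA replicates 1, 2 and 3 and LA+RVT replicate 2. Over all tested genes the median log2 fold change was 0.036.

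Among protein-coding genes with the largest rises in the LA arm, CCDC144NL (ENSG00000205212, chromosome 17, 20836447 to 20896140 on GRCh38) was listed at 0.0200, 0 and 0 TPM in the LA libraries and at 53.5, 51.3 and 42.0 TPM with RVT (adjusted p = 6.78e-06), and what was sequenced there cannot be seen without the reads. UBE2S, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, rose from 63.4 ± 1.23 to 196 ± 28.5 TPM (log2 fold change 1.60 ± 0.10, adjusted p = 0.000302). NDUFAF8, an assembly factor of respiratory complex I, rose from 42.9 ± 2.57 to 144 ± 19.3 TPM (log2 fold change 1.72 ± 0.10, adjusted p = 0.000257). C4orf48 rose from 12.3 ± 4.71 to 48.4 ± 9.61 TPM (log2 fold change 1.95 ± 0.29, adjusted p = 0.00669). These last 3 genes also differed by more than 2-fold between single PGN libraries. KRT16, a keratin of activated squamous epithelium, rose from 63.7 ± 11.5 to 193 ± 27.4 TPM (log2 fold change 1.59 ± 0.15, adjusted p = 0.00137). The remaining genes of the largest rises were non-coding: FP671120.4 (log2 fold change 1.83 ± 0.29), the antisense gene AC037198.2 (1.77 ± 0.20) and MIR3689B (ENSG00000264163, 1.96 ± 0.53), the last at 15.4, 67.2 and 67.5 TPM in the RVT libraries and no longer called in 5 of the 6 fits that leave out 1 library.

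The largest fall of a protein-coding gene in the LA arm was that of CYP1B1 (log2 fold change -2.87 ± 0.16, adjusted p = 0.000232). SERPINB3, a serpin of squamous epithelia, fell from 10.6 ± 1.03 to 2.19 ± 0.0503 TPM (log2 fold change -1.86 ± 0.10, adjusted p = 0.000213). LYPD2 fell from 11.2 ± 1.37 to 2.40 ± 0.601 TPM (log2 fold change -1.85 ± 0.15, adjusted p = 0.000805). S100A8, a calprotectin subunit, fell from 12.2 ± 1.77 to 3.21 ± 1.55 TPM (log2 fold change -1.71 ± 0.28, adjusted p = 0.00951). The antisense gene AC022966.1 stood at 89.9, 43.0 and 36.7 TPM with LA and at 0, 2.59 and 1.46 TPM with RVT (adjusted p = 0.00226). AC019209.3 and the pseudogenes DNAJC19P5 and FGF7P5 also fell (log2 fold changes -2.29, -2.28 and -2.16), at mean levels of 6.93, 5.48 and 8.30 TPM with LA; the calls of AC019209.3 and FGF7P5 were each lost in 5 of the 6 fits that leave out 1 library. Pseudogenes share sequence with their parent genes, and whether reads were assigned by strand is not given in the sources used here, so the values of pseudogenes and antisense genes are uncertain.

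Cell cycle genes changed with RVT in the LA arm. Of the DNA replication and S phase list, 0 of 40 tested members rose and 18 fell (0 and 23 adjusted over the list alone). Replication genes had a median log2 fold change of -0.15 (camera adjusted p = 1.04e-14, and adjusted p = 0.0283 with an estimated correlation). PCNA (log2 fold change -0.44 ± 0.033, adjusted p = 0.000624) and the helicase subunit MCM6 (-0.41 ± 0.034, adjusted p = 0.000805) had the smallest p-values. Of the mitosis and G2/M list, 15 of 40 tested members rose and 0 fell (18 and 1 adjusted over the list alone). Mitotic genes had a median log2 fold change of 0.12 (camera adjusted p = 0.000224, and adjusted p = 0.119 with an estimated correlation). CKS2, a cyclin-dependent kinase subunit, rose by 0.39 ± 0.033 and ANLN, a cytokinesis protein, by 0.25 ± 0.030. Among immediate early genes, 12 of 18 tested members rose and 0 fell (13 and 2 adjusted over the list alone). Immediate early genes had a median log2 fold change of 0.33 (camera adjusted p = 2.00e-06, and adjusted p = 0.0648 with an estimated correlation). EGR1 had a log2 fold change of 1.53 ± 0.055 (adjusted p = 5.90e-05) and MYC one of 0.71 ± 0.041 (adjusted p = 0.000256). Among p53 targets, 1 of 24 tested members rose and 5 fell (2 and 5 adjusted over the list alone). p53 targets had a median log2 fold change of -0.092 (camera adjusted p = 0.0207, and adjusted p = 0.119 with an estimated correlation). DDB2, a DNA damage recognition gene, changed by -0.46 and the kinase gene PLK3 by 0.38.

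Of the inflammatory cytokines and NF-kB targets, 5 of 29 tested members rose and 13 fell (8 and 14 adjusted over the list alone). Inflammatory genes had a median log2 fold change of -0.20 (camera adjusted p = 0.000211, and adjusted p = 0.0736 with an estimated correlation). The members with the smallest p-values went both ways. S100A9, the other calprotectin subunit, fell from 349 ± 8.16 to 189.9 ± 3.16 TPM (log2 fold change -0.88 ± 0.028, adjusted p = 4.54e-05). The acute-phase gene SAA2 fell from 161 ± 0.960 to 87.2 ± 3.63 TPM (log2 fold change -0.88 ± 0.037, adjusted p = 8.05e-05). TNFAIP2 fell from 259 ± 14.0 to 119 ± 9.24 TPM (log2 fold change -1.11 ± 0.064, adjusted p = 0.000244). MMP9, a gelatinase, rose from 6.27 ± 0.383 to 16.9 ± 1.40 TPM (log2 fold change 1.29 ± 0.084, adjusted p = 0.000387). The interleukin gene IL1A fell from 12.9 ± 0.301 to 9.80 ± 0.275 TPM (adjusted p = 0.0110). IL1B stood at 14.2 ± 1.02 and 12.7 ± 1.06 TPM (adjusted p = 0.268). CXCL1 went the other way, with a mean TPM 1.36 times as high with RVT as without. CXCL8 and IL6 were added to the named genes after their values were seen. CXCL8 fell from 10.3 ± 1.04 to 7.65 ± 0.220 TPM (log2 fold change -0.39 ± 0.087, adjusted p = 0.0286), a call that was lost without any 1 of the 6 libraries and without a filter (adjusted p = 0.0687). IL6 stood at 32.8 ± 1.48 and 27.3 ± 2.31 TPM (adjusted p = 0.0534) and was called lower under 6 of 14 alternatives, such as equalised library medians (adjusted p = 0.0358). In the interferon response list, 2 of 35 tested members rose and 8 fell (3 and 10 adjusted over the list alone). Interferon genes had a median log2 fold change of -0.069 (camera adjusted p = 0.000497, and adjusted p = 0.157 with an estimated correlation). IFITM1 changed by -0.64 ± 0.039 and IFITM3 by -0.43 ± 0.025, both membrane proteins that restrict virus entry. Of the NRF2 targets, an antioxidant programme, 5 of 20 tested members rose and 0 fell (7 and 1 adjusted over the list alone). NRF2 targets had a median log2 fold change of 0.10 (camera adjusted p = 0.00982, and adjusted p = 0.119 with an estimated correlation). SRXN1 rose by 0.42 ± 0.038 and TXNRD1 by 0.33 ± 0.025.

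Lipid genes changed little in the LA arm. Of the cholesterol synthesis and uptake list, 6 of 25 tested members rose and 1 fell (7 and 1 adjusted over the list alone). Sterol genes had a median log2 fold change of 0.074 (camera adjusted p = 0.0297, and adjusted p = 0.125 with an estimated correlation). The sterol synthesis enzymes CYP51A1 (0.32 ± 0.039), IDI1 (0.23 ± 0.040) and MSMO1 (0.21 ± 0.035) rose on the log2 scale. The list was not called with library medians equalised (camera adjusted p = 0.154), with the GC and length trend removed (0.0909) or without LA replicate 3 (0.0646) or LA+RVT replicate 3 (0.0621). Of the fatty acid and triglyceride synthesis list, 3 of 23 tested members rose and 1 fell (5 and 1 adjusted over the list alone), and camera did not call it (camera adjusted p = 0.118). Of the fatty acid oxidation and PPAR targets, 1 of 22 tested members rose and 3 fell (1 and 4 adjusted over the list alone). Oxidation genes had a median log2 fold change of -0.064 (camera adjusted p = 0.0413, and adjusted p = 0.157 with an estimated correlation). This list's call was lost in 4 of the 6 fits that leave out 1 library. PDK4, which restrains pyruvate oxidation, fell from 2.25 ± 0.348 to 0.880 ± 0.202 TPM (log2 fold change -0.79 ± 0.17, adjusted p = 0.0245), a call also lost in 4 of these fits (adjusted p 0.0657 to 0.0882). The nuclear receptor gene PPARD rose from 27.4 ± 0.435 to 33.1 ± 1.29 TPM (log2 fold change 0.27 ± 0.047, adjusted p = 0.0126). The catalytic AMPK subunit genes and SIRT1 were not called. RNA levels do not measure AMPK activity. PRKAA1 stood at 99.6 ± 10.6 TPM with LA and 114 ± 9.05 TPM with RVT (adjusted p = 0.189). PRKAA2 stood at 2.29 ± 0.176 and 2.21 ± 0.292 TPM (adjusted p = 0.874), and SIRT1 at 7.75 ± 0.585 and 7.80 ± 0.609 TPM (adjusted p = 0.970).

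Ribosomal protein genes took 13.8% ± 0.261 of all TPM with LA and 12.3% ± 0.130 with RVT. Of the cytosolic ribosomal protein list, 1 of 73 tested members rose and 54 fell (1 and 58 adjusted over the list alone). Ribosomal protein genes had a median log2 fold change of -0.17 (camera adjusted p = 2.23e-33, and adjusted p = 0.119 with an estimated correlation). RPS29 changed by -0.75 ± 0.041. Mitochondrially encoded transcripts took 14.0% ± 0.286 of TPM with LA and 13.1% ± 0.171 with RVT. Of the mitochondrially encoded list, 1 of 13 tested members rose and 8 fell (2 and 8 adjusted over the list alone). Mitochondrial genes had a median log2 fold change of -0.10 (camera adjusted p = 2.18e-05, and adjusted p = 0.119 with an estimated correlation). MT-CO1 changed by -0.32 ± 0.025 and MT-CO3 by -0.29 ± 0.011. Most markers of immune cells, fibroblasts, endothelium and melanocytes lay near 0, and those lists had fewer than 5 tested members in either arm. Exceptions, chosen after their values were seen, included the lysosomal macrophage marker CD68 (46.6 ± 2.11 TPM with LA and 54.2 ± 2.06 TPM with RVT) and the melanocyte genes MITF (18.3 ± 1.19 TPM with LA) and PMEL (6.85 ± 0.834 TPM). Of the fibroblast genes, COL1A1 stood at 6.72 ± 0.696 TPM and THY1 at 5.74 ± 2.16 TPM with LA. CD74 fell from 15.3 ± 1.47 to 4.59 ± 0.497 TPM (log2 fold change -1.54 ± 0.10, adjusted p = 0.000398) and the endothelial cadherin gene CDH5 fell from 16.9 ± 0.182 to 6.69 ± 0.584 TPM (log2 fold change -1.22 ± 0.076, adjusted p = 0.000328). The remaining lists were not called by camera in the LA arm. Lipid droplet and lipolysis had 3 up and 0 down of 12 (camera adjusted p = 0.608) and AMPK complex and regulators had 0 up and 1 down of 15 (camera adjusted p = 0.660). Sebocyte differentiation had 2 up and 1 down of 13 (camera adjusted p = 0.995) and pattern recognition receptors and adaptors had 2 up and 2 down of 18 (camera adjusted p = 0.354). Integrated stress response and unfolded protein response had 6 up and 2 down of 25 (camera adjusted p = 0.589) and hypoxia and glycolysis had 4 up and 3 down of 21 (camera adjusted p = 0.608). Autophagy and lysosome had 3 up and 1 down of 22 (camera adjusted p = 0.660) and estrogen receptor targets had 2 up and 0 down of 7 (camera adjusted p = 0.163). Keratinocyte and squamous differentiation had 2 up and 3 down of 13 (camera adjusted p = 0.784) and replication-dependent histones had 0 up and 0 down of 7 (camera adjusted p = 0.834). The median, mean and test of the lipid droplet, AMPK, sebocyte and keratinocyte lists differed in sign. The aryl hydrocarbon receptor list had fewer than 5 tested members there, and CYP1A1 stood at 1.36 ± 0.410 TPM with LA and 0.277 ± 0.176 TPM with RVT.

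The second comparison set PGN with RVT against PGN alone, and asked what resveratrol did under the inflammatory stimulus. Of the cytokine and NF-kB target genes 29 of 33 fell, and 24 of 25 cholesterol genes and 13 of 22 fatty acid synthesis genes rose. No list kept its camera call in this arm with an estimated correlation (adjusted p = 0.0528, 0.0528 and 0.124 for these 3). IL1B fell from 91.0 ± 6.55 to 8.52 ± 1.03 TPM (log2 fold change -3.27 ± 0.094, adjusted p = 5.73e-06) with n = 3 per group. IL1A fell from 80.1 ± 12.6 to 4.22 ± 0.0462 TPM (log2 fold change -3.95 ± 0.11, adjusted p = 5.73e-06). HMGCS1, which makes the HMG-CoA used for sterol synthesis, rose from 112 ± 2.86 to 198 ± 8.68 TPM (log2 fold change 0.82 ± 0.047, adjusted p = 0.000153). Of 14622 genes tested with limma, 1557 were higher and 720 lower with RVT at an adjusted p under 0.05. At least a 2-fold change was seen in 111 of them, 28 higher and 83 lower. With library medians equalised, 850 were higher and 1020 lower, and with the GC and length trend removed 1135 and 1212. The total of 2277 fell to 1384 without a filter, and to 1236, 1095, 1174 and 1201 without PGN replicate 2 and PGN+RVT replicates 1, 2 and 3.

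Of the inflammatory cytokines and NF-kB targets in the PGN arm, 0 of 33 tested members rose and 29 fell (0 and 29 adjusted over the list alone). Inflammatory genes had a median log2 fold change of -1.28 (camera adjusted p = 1.70e-37, and adjusted p = 0.0528 with an estimated correlation). The chemokine gene CXCL1 fell from 691 ± 70.5 to 91.9 ± 4.78 TPM (log2 fold change -2.89 ± 0.079, adjusted p = 5.63e-06). CXCL10 fell from 19.3 ± 1.90 to 0.773 ± 0.218 TPM (log2 fold change -3.52 ± 0.13, adjusted p = 2.36e-05). CCL20 fell from 11.9 ± 3.52 to 0.357 ± 0.160 TPM (log2 fold change -3.22 ± 0.21, adjusted p = 0.000249). TNFAIP2 fell from 669 ± 11.1 to 218 ± 8.15 TPM (log2 fold change -1.62 ± 0.039, adjusted p = 3.22e-06). CXCL8, which encodes interleukin 8, fell from 233 ± 43.2 to 25.8 ± 1.16 TPM (log2 fold change -3.11 ± 0.12, adjusted p = 2.44e-05). IL6 fell from 109.7 ± 8.96 to 39.9 ± 2.14 TPM (log2 fold change -1.44 ± 0.073, adjusted p = 8.64e-05). CYP1B1 fell from 86.2 ± 4.71 to 2.89 ± 0.284 TPM (log2 fold change -4.49 ± 0.080, adjusted p = 1.05e-06). CYP1A1 fell from 23.5 ± 1.19 to 0.377 ± 0.253 TPM (log2 fold change -4.17 ± 0.15, adjusted p = 1.72e-05). Both encode cytochromes P450 induced through the aryl hydrocarbon receptor, and of that receptor's targets 1 of 5 tested members rose and 3 fell (1 and 3 adjusted over the list alone). Receptor targets had a median log2 fold change of -1.47 (camera adjusted p = 0.000672, and adjusted p = 0.144 with an estimated correlation). Of the interferon response list, 10 of 33 tested members rose and 1 fell (14 and 1 adjusted over the list alone). Interferon genes had a median log2 fold change of 0.23 (camera adjusted p = 0.000947, and adjusted p = 0.144 with an estimated correlation). ISG15, a ubiquitin-like antiviral protein, changed by 0.37 ± 0.036 and the transcription factor gene IRF1 by -0.69 ± 0.061.

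**Figure D1:**
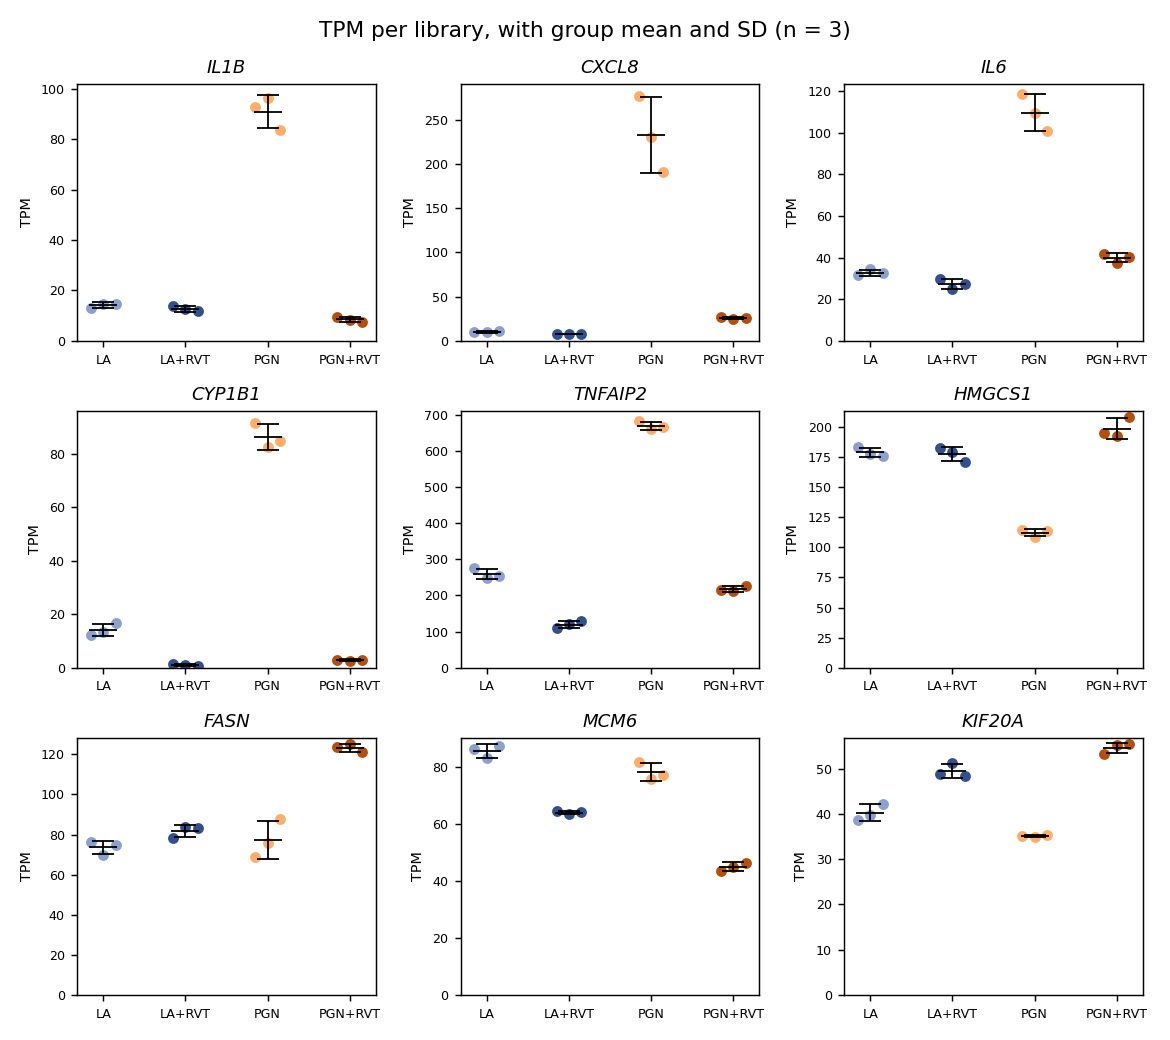
TPM (vertical axes, linear, from 0) of 9 genes in each library of the 4 groups; points are libraries, long bars the group mean and short bars the SD (n = 3). IL1B, CXCL8 and IL6 were high with PGN and lower with PGN and RVT, and changed far less between LA and LA with RVT.

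Most cholesterol genes rose in the PGN arm. Of the cholesterol synthesis and uptake list, 24 of 25 tested members rose and 0 fell (24 and 0 adjusted over the list alone). Sterol genes had a median log2 fold change of 0.61 (camera adjusted p = 1.54e-17, and adjusted p = 0.0528 with an estimated correlation). Beside HMGCS1, the squalene synthase gene FDFT1 rose from 148 ± 5.06 to 218 ± 5.59 TPM (log2 fold change 0.56 ± 0.043, adjusted p = 0.000473). ACAT2 rose from 81.7 ± 1.01 to 123 ± 4.48 TPM (log2 fold change 0.58 ± 0.045, adjusted p = 0.000473). Of the fatty acid and triglyceride synthesis list, 13 of 22 tested members rose and 0 fell (15 and 0 adjusted over the list alone). Fatty acid synthesis genes had a median log2 fold change of 0.37 (camera adjusted p = 1.13e-07, and adjusted p = 0.124 with an estimated correlation). FADS2, the desaturase that makes sapienic acid in sebum, rose from 56.7 ± 6.30 to 119.7 ± 6.82 TPM (log2 fold change 1.07 ± 0.084, adjusted p = 0.000499). Fatty acid synthase (FASN) rose from 77.4 ± 9.47 to 123 ± 2.01 TPM (log2 fold change 0.67 ± 0.084, adjusted p = 0.00307). ACSS2 rose from 62.9 ± 1.97 to 91.9 ± 2.45 TPM (log2 fold change 0.54 ± 0.047, adjusted p = 0.000796). ACLY rose from 115 ± 3.50 to 156 ± 6.20 TPM (log2 fold change 0.44 ± 0.047, adjusted p = 0.00168). Genes with a high GC content had higher log2 fold changes in this arm (Spearman's rho across genes 0.199, genes not being independent replicates). The catalytic AMPK subunit genes PRKAA1 and PRKAA2 and SIRT1 were not called. PRKAA1 stood at 77.1 ± 8.96 TPM with PGN and 87.3 ± 8.18 TPM with RVT (adjusted p = 0.266), and with the GC and length trend removed it was called higher (log2 fold change 0.21, adjusted p = 0.0377). PRKAA2 stood at 1.09 ± 0.113 and 1.13 ± 0.0656 TPM (adjusted p = 0.926), and SIRT1 at 5.87 ± 0.491 and 7.15 ± 0.946 TPM (adjusted p = 0.196).

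Cell cycle genes were called in both directions. Of the DNA replication and S phase list, 0 of 40 tested members rose and 20 fell (1 and 25 adjusted over the list alone). Replication genes had a median log2 fold change of -0.26 (camera adjusted p = 1.75e-16, and adjusted p = 0.0528 with an estimated correlation). Lowest p-values were those of the helicase subunits MCM6 (-0.79 ± 0.053) and MCM5 (-0.75 ± 0.050). In the mitosis and G2/M list, 23 of 40 tested members rose and 0 fell (28 and 0 adjusted over the list alone). Mitotic genes had a median log2 fold change of 0.33 (camera adjusted p = 1.97e-09, and adjusted p = 0.175 with an estimated correlation). Among the mitotic genes, the smallest p-values were those of the kinesin KIF20A (0.62 ± 0.047) and the kinase gene PLK1 (0.51 ± 0.049). Among hypoxia and glycolysis genes, 0 of 21 tested members rose and 6 fell (0 and 9 adjusted over the list alone). Hypoxia genes had a median log2 fold change of -0.13 (camera adjusted p = 4.95e-06, and adjusted p = 0.0528 with an estimated correlation). VEGFA, an angiogenic factor, fell from 55.3 ± 1.46 to 33.9 ± 1.98 TPM (log2 fold change -0.69 ± 0.060, adjusted p = 0.000747). Lactate dehydrogenase A (LDHA) fell from 1100.2 ± 89.2 to 787 ± 20.6 TPM (log2 fold change -0.48 ± 0.058, adjusted p = 0.00282). Among keratinocyte and squamous differentiation genes, 2 of 14 tested members rose and 6 fell (2 and 6 adjusted over the list alone). Squamous genes had a median log2 fold change of -0.17 (camera adjusted p = 0.00147, and adjusted p = 0.124 with an estimated correlation). Filaggrin (FLG) changed by -1.86 ± 0.11 and SPRR1B, a cornified envelope precursor, by -0.89 ± 0.064. Of the sebocyte differentiation list, 1 of 12 tested members rose and 3 fell (1 and 4 adjusted over the list alone). Sebocyte genes had a median log2 fold change of -0.045 (camera adjusted p = 0.0369, and adjusted p = 0.159 with an estimated correlation). This call was also lost with equalised medians (camera adjusted p = 0.101), with the GC and length trend removed (0.125) and without PGN replicate 2 (0.0905) or PGN+RVT replicate 3 (0.117). The lipogenic nuclear receptor gene PPARG fell from 38.7 ± 0.832 to 23.1 ± 0.864 TPM (log2 fold change -0.72 ± 0.056, adjusted p = 0.000473). PRDM1 fell from 6.96 ± 0.601 to 3.42 ± 0.378 TPM (log2 fold change -0.85 ± 0.11, adjusted p = 0.00373).

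The largest rises in the PGN arm included CITED2, a transcriptional co-regulator, which rose from 9.38 ± 1.11 to 28.5 ± 0.990 TPM (log2 fold change 1.51 ± 0.089, adjusted p = 0.000173). ID2, an inhibitor of helix-loop-helix factors, rose from 9.78 ± 1.64 to 24.1 ± 2.03 TPM (log2 fold change 1.23 ± 0.12, adjusted p = 0.00131). PRR15L rose from 3.63 ± 0.576 to 11.3 ± 0.699 TPM (log2 fold change 1.41 ± 0.12, adjusted p = 0.000561). SPTSSB, a small subunit of the enzyme that starts sphingolipid synthesis, rose from 1.33 ± 0.594 to 6.58 ± 2.50 TPM (log2 fold change 1.68 ± 0.27, adjusted p = 0.00842). The antisense gene AL049840.3 had a log2 fold change of 1.22 ± 0.32, a call lost in 5 of the 6 fits that leave out 1 library. Other extreme genes were listed at 0 in a whole group. SNORD15B (chromosome 11, 75404421 to 75404566 on GRCh38) stood at 41.8, 51.9 and 57.4 TPM with PGN and was listed at 0 in the other 9 libraries. TPM divides by transcript length, so few reads can give a high TPM for short genes such as SNORD15B. Read numbers are not available here. SNORA71 was listed at 0 in 9 libraries and at 42.8, 14.7 and 86.2 TPM with PGN and RVT. AC079741.2 stood at 58.9, 29.2 and 7.02 TPM with PGN and was listed at 0 with PGN and RVT. The pseudogenes AC006262.4 and AL031281.1 were listed at 0 with PGN and at 2.58, 6.79 and 7.47 TPM and 0.690, 12.6 and 6.54 TPM with RVT, and the call of AL031281.1 was lost in 5 of the 6 fits that leave out 1 library.

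Ribosomal protein genes took 15.0% ± 0.132 of TPM with PGN and 14.3% ± 0.305 with RVT. Of that list, 0 of 73 tested members rose and 22 fell (0 and 29 adjusted over the list alone). Ribosomal protein genes had a median log2 fold change of -0.083 (camera adjusted p = 1.64e-12, and adjusted p = 0.134 with an estimated correlation). RPSA changed by -0.17 ± 0.025 and RPS15A by -0.17 ± 0.026. Mitochondrially encoded transcripts took 11.5% ± 0.215 and 10.7% ± 0.518 of TPM. Of their list, 0 of 13 tested members rose and 4 fell (0 and 5 adjusted over the list alone). Mitochondrial genes had a median log2 fold change of -0.081 (camera adjusted p = 0.000672, and adjusted p = 0.326 with an estimated correlation). The call was also lost with fry (adjusted p = 0.0654) and with the GC and length trend removed (camera adjusted p = 0.0730). MT-CO3 changed by -0.28 ± 0.031 and MT-ND3 by -0.29 ± 0.035. Without a filter, RPS15A (adjusted p = 0.0759) and MT-CO3 (0.0705) were not called. CD74 stood at 4.76 ± 0.376 and 4.06 ± 1.07 TPM without and with RVT (adjusted p = 0.436), and CDH5 at 24.8 ± 1.06 and 22.9 ± 0.592 TPM (adjusted p = 0.262). With the GC and length trend removed, CDH5 was called lower (log2 fold change -0.21, adjusted p = 0.0321). Camera did not call the other lists in the PGN arm. Lipid droplet and lipolysis had 5 up and 2 down of 11 (camera adjusted p = 0.413) and fatty acid oxidation and PPAR targets had 4 up and 2 down of 21 (camera adjusted p = 0.0784). AMPK complex and regulators had 0 up and 2 down of 15 (camera adjusted p = 0.487) and pattern recognition receptors and adaptors had 1 up and 1 down of 18 (camera adjusted p = 0.426). NRF2 targets had 9 up and 3 down of 20 (camera adjusted p = 0.115) and p53 targets had 4 up and 3 down of 23 (camera adjusted p = 0.905). Integrated stress response and unfolded protein response had 4 up and 6 down of 25 (camera adjusted p = 0.189) and autophagy and lysosome had 5 up and 1 down of 22 (camera adjusted p = 0.0847). Estrogen receptor targets had 2 up and 1 down of 7 (camera adjusted p = 0.787) and immediate early genes had 6 up and 6 down of 19 (camera adjusted p = 0.755). Replication-dependent histones had 1 up and 0 down of 10 (camera adjusted p = 0.723). The median, mean and test of the AMPK, pattern recognition, stress response, estrogen receptor and immediate early lists differed in sign.

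**Figure D2:**
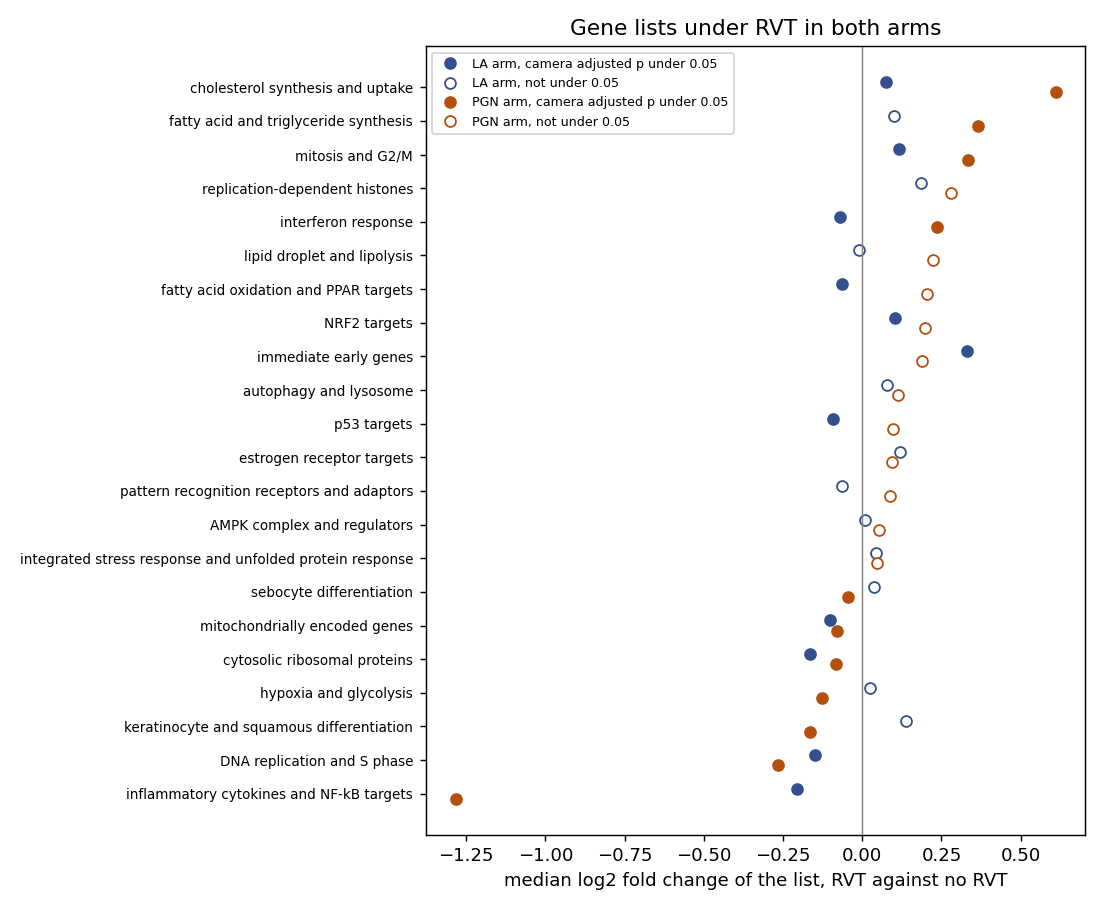
Median log2 fold change with RVT of each gene list tested in both arms (horizontal axis) in the LA arm (blue) and the PGN arm (orange); filled points are lists with a camera adjusted p under 0.05. The inflammatory list lay at -1.28 in the PGN arm and at -0.20 in the LA arm, and the cholesterol list at 0.61 and 0.074.

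The third comparison tested whether the RVT effect differed between the arms, as the log2 fold change in the LA arm minus that in the PGN arm. Most cytokine genes had a more negative RVT effect in the PGN arm, and most sterol genes a more positive one. For IL1A the difference was 3.58 ± 0.13 (adjusted p = 4.99e-08), for CXCL1 3.32 ± 0.12 (adjusted p = 4.99e-08), for CXCL8 2.72 ± 0.16 (adjusted p = 1.84e-06) and for IL6 1.18 ± 0.11 (adjusted p = 4.09e-05). Of 15177 genes tested with limma over the 12 libraries, 1067 had a positive and 1173 a negative difference at an adjusted p under 0.05. Of the inflammatory list, 28 of 33 tested members had a positive and 4 a negative difference past the threshold (28 and 4 adjusted over the list alone). Inflammatory genes differed by a median of 0.94 (camera adjusted p = 7.18e-21, and adjusted p = 0.00983 with an estimated correlation). In the cholesterol list, 0 of 25 tested members had a positive and 22 a negative difference past the threshold (0 and 24 adjusted over the list alone). Sterol genes differed by a median of -0.50 (camera adjusted p = 4.32e-18, and adjusted p = 0.00983 with an estimated correlation). In the fatty acid and triglyceride synthesis list, 0 of 23 tested members had a positive and 10 a negative difference past the threshold (0 and 13 adjusted over the list alone). Fatty acid synthesis genes differed by a median of -0.22 (camera adjusted p = 7.90e-05, and adjusted p = 0.0546 with an estimated correlation). In the interferon response list, 0 of 34 tested members had a positive and 13 a negative difference past the threshold (0 and 17 adjusted over the list alone). Interferon genes differed by a median of -0.38 (camera adjusted p = 2.49e-06, and adjusted p = 0.0170 with an estimated correlation). Stimulus, table and any batch that follows the table coincide, so a difference between arms cannot be assigned to the stimulus alone.

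Further lists also differed between the arms. Among hypoxia and glycolysis genes, 8 of 21 tested members had a positive and 0 a negative difference past the threshold (9 and 0 adjusted over the list alone). Hypoxia genes differed by a median of 0.19 (camera adjusted p = 7.90e-05, and adjusted p = 0.0115 with an estimated correlation). Among immediate early genes, 9 of 18 tested members had a positive and 3 a negative difference past the threshold (10 and 4 adjusted over the list alone). Immediate early genes differed by a median of 0.33 (camera adjusted p = 4.40e-05, and adjusted p = 0.0115 with an estimated correlation). Of the aryl hydrocarbon receptor targets, 3 of 5 tested members had a positive and 0 a negative difference past the threshold (3 and 1 adjusted over the list alone). Receptor targets differed by a median of 1.39 (camera adjusted p = 0.000784, and adjusted p = 0.0546 with an estimated correlation). In the fatty acid oxidation list, 0 of 21 tested members had a positive and 6 a negative difference past the threshold (0 and 8 adjusted over the list alone). Oxidation genes differed by a median of -0.19 (camera adjusted p = 0.00770, and adjusted p = 0.0546 with an estimated correlation). The cell cycle lists differed by less. Of the replication list, 5 of 40 tested members had a positive and 1 a negative difference past the threshold (5 and 1 adjusted over the list alone). Replication genes differed by a median of 0.095 (camera adjusted p = 0.0157, and adjusted p = 0.212 with an estimated correlation). Of the mitosis list, 1 of 40 tested members had a positive and 13 a negative difference past the threshold (1 and 16 adjusted over the list alone). Mitotic genes differed by a median of -0.17 (camera adjusted p = 5.67e-05, and adjusted p = 0.212 with an estimated correlation). Of the ribosomal protein list, 1 of 73 tested members had a positive and 21 a negative difference past the threshold (1 and 22 adjusted over the list alone). Ribosomal protein genes differed by a median of -0.059 (camera adjusted p = 0.000355, and adjusted p = 0.364 with an estimated correlation). By size, the largest positive differences past the threshold were those of AC079741.2, SNORD15B, CCDC144NL, IL1A and CXCL1, and the largest negative ones those of SNORA71, AL031281.1, AC006262.4, SPTSSB (-2.55 ± 0.62) and the antisense gene AP003119.2 (-1.98 ± 0.52). Leaving out 1 of the 12 libraries at a time, the calls of AL031281.1, AC079741.2 and AP003119.2 were lost in 10, 8 and 6 fits. PRKAA1 (0.016, adjusted p = 0.964), PRKAA2 (-0.070, adjusted p = 0.844) and SIRT1 (-0.24, adjusted p = 0.321) were not called. For the difference, camera called none of the remaining lists. Lipid droplet and lipolysis had 3 positive and 4 negative of 11 (camera adjusted p = 0.953) and AMPK complex and regulators had 3 positive and 1 negative of 15 (camera adjusted p = 0.772). Sebocyte differentiation had 3 positive and 0 negative of 13 (camera adjusted p = 0.116) and pattern recognition receptors and adaptors had 1 positive and 3 negative of 18 (camera adjusted p = 0.953). NRF2 targets had 4 positive and 3 negative of 20 (camera adjusted p = 0.953) and p53 targets had 5 positive and 7 negative of 24 (camera adjusted p = 0.135). Integrated stress response and unfolded protein response had 5 positive and 3 negative of 25 (camera adjusted p = 0.186) and autophagy and lysosome had 0 positive and 3 negative of 22 (camera adjusted p = 0.119). Estrogen receptor targets had 2 positive and 1 negative of 7 (camera adjusted p = 0.116) and keratinocyte and squamous differentiation had 5 positive and 2 negative of 14 (camera adjusted p = 0.260). Mitochondrially encoded genes had 0 positive and 1 negative of 13 (camera adjusted p = 0.953) and replication-dependent histones had 0 positive and 0 negative of 8 (camera adjusted p = 0.753). Here the median, mean and test of the lipid droplet, sebocyte, pattern recognition and keratinocyte lists differed in sign.

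The last comparison asked how far the 2 arms shared their response to RVT. CYP1B1, TNFAIP2, CXCL10, S100A8 and SERPINB3 were lower with RVT in both arms, PCNA and MCM6 likewise, and EGR1 rose in both, although the sizes differed for several of them. Among 14126 genes tested in both arms, 318 were called higher in both and 169 lower in both, against 179.5 and 38.0 for independent lists (Fisher's exact test, two-sided, p = 3.85e-27 and 1.82e-66). Another 106 were higher in the LA arm and lower in the PGN arm, against 81.0 for independent lists (Fisher's exact test p = 0.00355). The other way round there were 79, against 84.2 (Fisher's exact test p = 0.593). Over all tested genes the log2 fold changes of the arms had low correlations (across genes, Pearson's r 0.0854 and Spearman's rho 0.106). Leaving out 1 library at a time, r ran from 0.0506 to 0.0998, and the number of genes called in the same direction in both arms, 487, from 282 to 438. The arms share no libraries, and genes are not independent replicates. With library medians equalised, the genes called higher fell from 1645 to 1041 in the LA arm and from 1557 to 850 in the PGN arm. The overlap was not computed with that scaling, so how far the 318 genes depend on it is unknown.

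**Figure D3:**
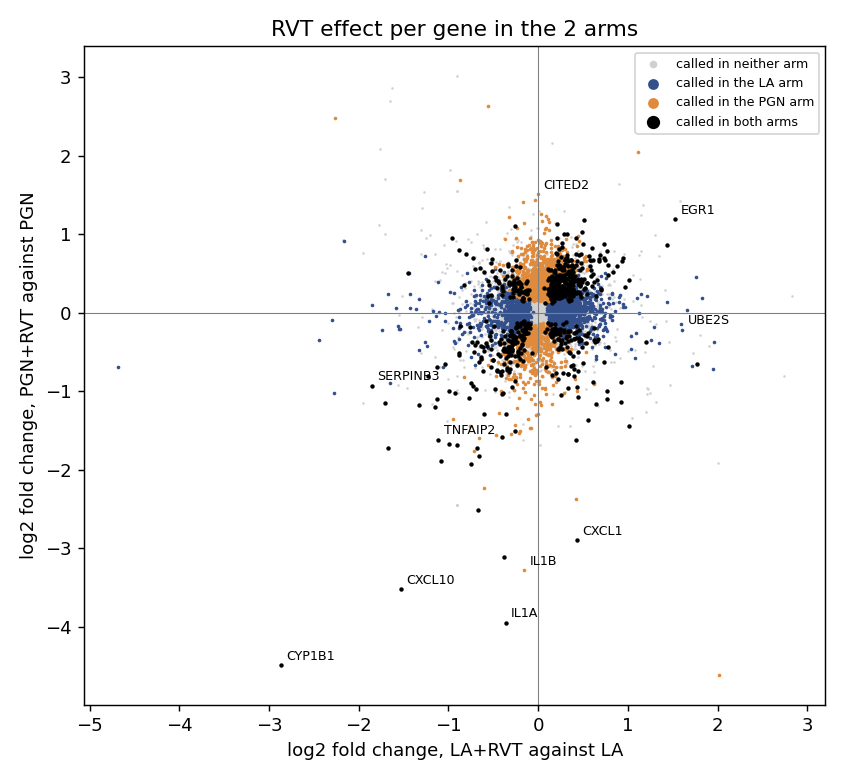
Log2 fold change with RVT of each gene tested in both arms, in the LA arm (horizontal axis) and the PGN arm (vertical axis); colours mark genes called in neither, one or both arms at an adjusted p under 0.05. CYP1B1, CXCL10 and TNFAIP2 lie low in both arms, while IL1A and IL1B lie low in the PGN arm and near 0 in the LA arm.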

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

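A result is given here when the RVT effect differed between the arms in the test of the difference itself; each value is the effect in the LA arm minus that in the PGN arm on the log2(TPM + 1) scale. The tests of leukocyte RNA and of library scaling were chosen only after the result was seen, the first form of the leukocyte test left out CD68 and CD74, whose values were known, and is replaced here by all markers of the list, and the GC and length correction was an alternative added after the data were seen. Among cytokine and NF-kB genes the difference was positive for IL1A (3.58), CXCL1 (3.32), IL1B (3.12), CXCL8 (2.72), CCL20 (2.71), CXCL10 (1.99), MMP9 (1.48), IL6 (1.18) and TNFAIP2 (0.50), and negative for SAA2 (-0.83) and S100A9 (-0.71). Where a group lies near or under 1 TPM, as for CCL20, CXCL10, CYP1A1, CYP1B1, FLG and SPTSSB, the size depends on the pseudocount. For CCL20, under 1 TPM in all LA arm libraries, the ratio of means without over with RVT was 9.38 there and 33.4 in the PGN arm. The whole inflammatory list had a median difference of 0.94. 

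Some positive differences include a rise with RVT in the LA arm, as for MMP9 and CXCL1. Their mean TPM with RVT over without was 2.69 and 1.36 there, and 5 of 29 list members were called higher. The more negative RVT effect on inflammatory genes in the PGN arm was set against 3 technical explanations, the last by description only. With the GC and length trend of each library removed, the list's median difference was 0.999 (camera adjusted p = 3.08e-20), which argues against such a trend as the whole cause. Compression of low values in the LA arm by the pseudocount is argued against by the 23 members with at least 10 TPM in both groups without RVT, whose median difference was 0.82 and of which 18 had a positive difference past the threshold. The libraries come from a cell line, and the leukocyte test was written after the marker values were known, so it is only a description. The highest values of the 9 fixed immune cell markers in a PGN library had a median of 0.18 TPM beside 91.0 TPM of IL1B. Of these markers, 7 were under 1 TPM. The exceptions were CD74, at up to 5.07 TPM, and CD68, at up to 33.9 TPM, which rose with RVT (log2 fold change 0.60). A hypothesis that stays open, and that untreated cells and cells with RVT alone in the same experiment would test, is that RVT may act mainly on cytokine expression under an inflammatory stimulus; stimulus, table and any batch cannot be told apart and no untreated group gives the level without stimulus.

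Among sterol genes the difference was negative for HMGCS1 (-0.83), MSMO1 (-0.74), IDI1 (-0.58), ACAT2 (-0.50), FDFT1 (-0.45) and CYP51A1 (-0.41), and the cholesterol list had a median of -0.50. Among genes of fatty acid synthesis it was negative for FADS2 (-0.99), ACSS2 (-0.53), FASN (-0.52) and ACLY (-0.22), with a list median of -0.22, and the list of fatty acid oxidation and PPAR targets had a median of -0.19. Both list calls were lost with an estimated correlation (adjusted p = 0.0546 and 0.0546). The rise of the cholesterol list in the PGN arm was weighed because GC-rich genes moved up in that arm, from a median log2 fold change of 0.0066 in the tenth of genes with the lowest GC content to 0.14 in the highest. With the GC and length trend removed the list's median was 0.52, against 0.61 before, and camera at its preset correlation still called it (adjusted p = 1.13e-19), a call that the uncorrected values lose with an estimated correlation (adjusted p = 0.0528). The value with the trend removed argues against the trend as the whole cause. With equalised library medians the list's median was 0.55, which follows from a shift of all genes alike (their median from 0.064 to 0.0054) and tests nothing further. As a hypothesis, RVT may raise sterol gene expression under PGN more than under LA, which both arms and untreated cells processed in one batch would test; until then stimulus, table and batch cannot be told apart.

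In the cell cycle lists the difference had a median of 0.095 for DNA replication and -0.17 for mitosis, calls that were lost with an estimated correlation (adjusted p = 0.212 and 0.212). It was past the threshold for MCM6 (0.37), MCM5 (0.33), KIF20A (-0.33) and PLK1 (-0.33). The joint pattern of lower replication genes and higher mitotic genes was weighed in both arms by the gap between the list medians, mitosis minus replication. With the GC and length trend removed the gap was 0.28 in the LA arm and 0.63 in the PGN arm, against 0.27 and 0.60 before. Leaving out 1 library at a time, its lowest values were 0.25 without LA+RVT replicate 1 and 0.54 without PGN+RVT replicate 1. These values argue against a GC trend and against a single library as the source, while with an estimated correlation the mitosis list loses its own call in both arms (adjusted p = 0.119 and 0.175) and the replication list in the PGN arm (0.0528). As a hypothesis, fewer RVT-treated cells may be in S phase and more in G2 or mitosis, which a measurement of DNA content would test without telling G2 from mitosis.

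Of the other genes whose RVT effect differed between the arms, aryl hydrocarbon receptor genes had positive differences: CYP1A1 (3.28) and CYP1B1 (1.62), with a list median of 1.39 and 3 of 5 members past the threshold, a list call lost with an estimated correlation (adjusted p = 0.0546). Interferon-related genes had negative ones: IFITM1 (-0.87), IFITM3 (-0.80) and ISG15 (-0.70), with a list median of -0.38. Of the immediate early genes, 9 of 18 had a positive and 3 a negative difference, with MYC (0.80) and EGR1 (0.34) and a list median of 0.33. Hypoxia genes had 8 of 21 positive differences, with VEGFA (0.89) and LDHA (0.49) and a list median of 0.19. Single genes of lists that camera did not call for the difference are TXNRD1 and SRXN1 of the NRF2 targets (4 positive and 3 negative of 20 members past the threshold, adjusted p = 0.953), PLK3 and DDB2 of the p53 targets (5 positive and 7 negative of 24 members past the threshold, adjusted p = 0.135), FLG and SPRR1B of the keratinocyte list (5 positive and 2 negative of 14 members past the threshold, adjusted p = 0.260) and PPARG of the sebocyte list (3 positive and 0 negative of 13 members past the threshold, adjusted p = 0.116). Their differences were TXNRD1 (0.45), SRXN1 (0.30), PLK3 (0.50), DDB2 (-0.36), FLG (1.72), SPRR1B (1.5) and PPARG (0.67). Those of genes picked for the size of their change in the LA arm were KRT16 (1.73), LYPD2 (-1.95) and SERPINB3 (-0.93). Single ribosomal and mitochondrial genes with differences were RPS29 (-0.57) and MT-CO1 (-0.33). The ribosomal list had a median of -0.059, a call lost with an estimated correlation (adjusted p = 0.364), and camera did not call the mitochondrial list (adjusted p = 0.953). The markers CD74 and CDH5 had differences of -1.34 and -1.11. Genes with larger single values were AC037198.2 (2.42), C4orf48 (2.67), FP671120.4 (1.64), NDUFAF8 (2.39), UBE2S (1.82), CITED2 (-1.52), ID2 (-1.13), PRR15L (-1.58), SPTSSB (-2.55) and AP003119.2 (-1.98). For genes listed at 0 in all libraries of a group, or in nearly all, the fitted difference depends on the pseudocount and bounds no fold: AC079741.2 (6.62), SNORD15B (5.67), CCDC144NL (5.64), SNORA71 (-5.29), AL031281.1 (-4.75) and AC006262.4 (-3.19). The value of AC079741.2 rests partly on 1 LA+RVT library at 64.8 TPM, with the other 5 libraries of the LA arm listed at 0.

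Other splits of the libraries were fitted to see whether chance can be excluded. In the LA arm 1 of the 10 splits, the labelled one, gave 2426 genes, and the highest other split gave 1; for called lists the values were 11 and 3. In the PGN arm the labelled split gave 2277 genes and the highest other 2, and 12 lists against 10. For the difference, 1 drawn split that broke both arms' labels called 8 lists and 0 genes. Camera at its preset correlation thus called many lists in splits with almost no called genes. Within an arm such splits still divide the RVT libraries unequally, so part of the RVT effect can remain in them. With 10 splits per arm no share under 0.05 can be had. For the difference, 2 of 100 drawn splits (the labelled one included) gave as many genes as the labelled 2240. The other one, at 3666 genes, is the split that keeps both arms' labels and mirrors the PGN arm, so that it tests the sum of the effects. As many called lists, 11 or more (highest 12), came from 7 of 100 splits. Each of these splits kept the labelled groups of the PGN arm and with them its RVT effect. They therefore cannot show how many lists chance gives, and chance is neither shown nor excluded for that count. For genes called in both arms in the same direction, 1 of 100 splits gave as many as 487, and the highest other gave 185. All other splits gave 0 such genes, because an arm without its labels has almost no calls. Likewise, splits that broke the labels of at least 1 arm gave 0 to 823 genes for the difference. Both counts therefore reflect that each arm changed with RVT, and the splits do not show whether chance can be excluded for effects that differ or are shared.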

How the results depend on the processing

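The settings tested here were chosen in advance except the removal of mitochondrial genes and of the GC and length trend, which were added after the data were seen. Of 472 values of the 34 called lists under alternatives, 429 kept the direction and the call, 43 lost the call and 0 changed direction. Of 1632 values of the 112 named results per gene and comparison, 1521 kept both, 88 lost and 8 gained a call, and 15 changed direction. Counts of genes moved more. Without a filter, the LA arm had 1610 genes (1095 higher, 515 lower) and the PGN arm 1384 genes (900 higher), where more genes are tested. With equalised medians, 1041 genes were higher in the LA arm and 850 in the PGN arm. With the GC and length trend removed, 1212 genes were lower in the PGN arm. With the estimated correlation, camera called 1 list in the LA arm, 0 in the PGN arm and 5 in the difference; fry, which asks another question, called 18 in the LA arm and 18 in the difference.

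Leaving out 1 library at a time gave 1428 to 1690 genes in the LA arm (954 to 1144 higher, 457 to 547 lower), and the count fell by over 1.5 times without LA 1 (1459), LA 2 (1428), LA 3 (1463), LA+RVT 2 (1546). In the PGN arm it gave 1095 to 1861 (690 to 1270 higher, 405 to 599 lower), with such a fall without PGN 2 (1236), PGN+RVT 1 (1095), PGN+RVT 2 (1174), PGN+RVT 3 (1201). For the difference it gave 1714 to 2250 genes (833 to 1062 positive, 862 to 1188 negative), and for called lists 9 to 11 in the LA arm, 11 to 12 in the PGN arm and 11 to 12 in the difference. Genes called in both arms in the same direction numbered 282 to 438, and fell by over 1.5 times without LA 2 (309), LA 3 (309), PGN 2 (308), PGN+RVT 1 (282), PGN+RVT 2 (309), PGN+RVT 3 (294). Pearson's r between the arms ran from 0.0506, without PGN replicate 3, to 0.0998. Fewer libraries leave fewer residual degrees of freedom; beyond that, the cause was not tested. Single list calls lost this way were cholesterol synthesis in the LA arm without LA 3 (0.0646), LA+RVT 3 (0.0621), fatty acid oxidation in the LA arm without LA 1 (0.0703), LA 3 (0.0642), LA+RVT 2 (0.0510), LA+RVT 3 (0.0880), and sebocyte differentiation in the PGN arm without PGN 2 (0.0905), PGN+RVT 3 (0.117), each with its camera adjusted p. Leaving out single libraries also ended the call of named genes. These were CXCL8 in the LA arm (6 libraries, adjusted p 0.0507 to 0.0820), PDK4 in the LA arm (4 libraries, adjusted p 0.0657 to 0.0882), AC019209.3 in the LA arm (5 libraries, adjusted p 0.0686 to 0.0983), FGF7P5 in the LA arm (5 libraries, adjusted p 0.0885 to 0.124), MIR3689B in the LA arm (5 libraries, adjusted p 0.119 to 0.130), AL031281.1 in the PGN arm (5 libraries, adjusted p 0.0996 to 0.142), AL049840.3 in the PGN arm (5 libraries, adjusted p 0.0731 to 0.121), AL031281.1 in the difference (10 libraries, adjusted p 0.0532 to 0.0829), AP003119.2 in the difference (6 libraries, adjusted p 0.0518 to 0.0651) and AC079741.2 in the difference (8 libraries, adjusted p 0.0631 to 0.0753).

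These calls were also lost. Without a filter these were, in the LA arm CXCL8 (0.0687), AC019209.3 (0.0954), FGF7P5 (0.120), MIR3689B (0.129), in the PGN arm RPS15A (0.0759), AL031281.1 (0.151), AL049840.3 (0.140), MT-CO3 (0.0705) and in the difference AL031281.1 (0.104), AP003119.2 (0.0809), SPTSSB (0.0579), AC079741.2 (0.102). With equalised medians these were, in the LA arm cholesterol synthesis and uptake (0.154), MIR3689B (0.0588) and in the PGN arm sebocyte differentiation (0.101), AL031281.1 (0.0653), AL049840.3 (0.0511). With a pseudocount of 0.1 these were, in the LA arm AC019209.3 (0.0528), FGF7P5 (0.0941). With all 12 libraries in one fit these were, in the LA arm FGF7P5 (0.0979) and in the PGN arm AL031281.1 (0.0873). With the GC and length trend removed these were, in the LA arm cholesterol synthesis and uptake (0.0909), FGF7P5 (0.0575) and in the PGN arm sebocyte differentiation (0.125), mitochondrially encoded genes (0.0730), AL049840.3 (0.0730). With mitochondrial genes removed these were, in the LA arm MIR3689B (0.0523). With fry these were, in the PGN arm mitochondrially encoded genes (0.0654). Each p is adjusted.

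With the replicate number as a block, the LA arm had 1502 genes (997 higher, 505 lower), the PGN arm 1574 genes, the difference 1730, and 261 genes were called in both arms in the same direction. Calls lost with the block were, in the LA arm fatty acid oxidation and PPAR targets (0.0710), CXCL8 (0.0626), PDK4 (0.0806), AC019209.3 (0.0756), FGF7P5 (0.0509), MIR3689B (0.0685) and in the PGN arm AL031281.1 (0.0575), AL049840.3 (0.0663), each with its adjusted p. Correlations between same-numbered libraries' deviations from their group means were -0.0702, -0.00676 and -0.0288 in the LA arm. In the PGN arm they were 0.0324, 0.0407 and 0.00805, so all were under 0.05. They lay below the highest correlation with another number for each LA replicate and above it for each PGN replicate. These weak values do not settle whether the numbers pair the samples. The only values that changed direction were those of genes never called in that comparison: PRKAA2 in the LA arm (0.037 without LA+RVT replicate 2, left-out range -0.081 to 0.037), SIRT1 in the LA arm (-0.040 with equalised medians, -0.0046 with mitochondrial genes removed, -0.030 with the GC and length trend removed, -0.049 without LA replicate 1, -0.030 without LA+RVT replicate 1, -0.012 without LA+RVT replicate 3, left-out range -0.049 to 0.065), PRKAA2 in the PGN arm (-0.030 with equalised medians, -0.017 without PGN replicate 2, left-out range -0.017 to 0.053), PRKAA1 in the difference (-0.046 with the GC and length trend removed, -0.058 without LA replicate 2, -0.040 without LA+RVT replicate 1, -0.077 without PGN replicate 1, -0.057 without PGN+RVT replicate 2, left-out range -0.077 to 0.093) and PRKAA2 in the difference (0.0084 without LA+RVT replicate 2, left-out range -0.11 to 0.0084). The cause was not tested. The planned count-based tests were not run, because the tables hold TPM and no counts, and neither was any alternative of LA against PGN, which was not tested. Depth is unknown, so its limits on low genes cannot be given.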

Other observations

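Single PGN libraries differed for genes that rose in the LA arm with RVT. UBE2S stood at 108, 140.2 and 64.2 TPM in PGN replicates 1, 2 and 3, NDUFAF8 at 109, 131 and 58.5 TPM and C4orf48 at 20.6, 39.0 and 12.2 TPM. With PGN and RVT the same genes stood at 84.0, 85.8 and 85.5, at 66.0, 51.2 and 59.4 and at 15.3, 15.6 and 8.41 TPM. CCDC144NL was listed at over 10 TPM in the 3 LA+RVT libraries and in none of the other 9, and at 0 in all 3 libraries of PGN with RVT; the reads, not available here, would be needed to see what was sequenced. FP671120.4, a non-coding gene at chromosome 21, 8197620 to 8227646 on GRCh38, stood at 5.60, 4.89 and 5.12 TPM with LA and at 126, 231 and 171 TPM with PGN; the tables were made separately, and this level was not tested across them.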
